A study of Arabidopsis thaliana with 9 samples.

How the data were processed

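Messenger RNA was sequenced from whole 14-day-old *Arabidopsis thaliana* seedlings of 3 groups, Col, *thp1-5* and *sac3bc*, with 3 libraries each. According to the labels, seedlings grew on medium with 1% sucrose at 22 °C under 16 h light and 8 h dark, RNA was extracted with Trizol and selected for poly(A), and libraries made with the NEBNext mRNA Library Prep Reagent Set were sequenced on a HiSeq 2500 as single-end reads of 150 nt. The deposited unit was read counts per gene, with 1 table per library that also held a gene length. The authors' processing notes name STAR and DESeq2 without versions or roles. The genome build, annotation, counting program and strand setting are not given in the sources used here, so loci are named by identifier and no coordinates are printed. Of the 37361 loci, 37065 had a row in the reference gene table and the other 296 were organelle loci (134 of the chloroplast and 162 of the mitochondria). Of 37051 loci with exons in the reference, 99.51% had a length equal to the union of their exons in it.

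Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors and the robust quasi-likelihood F-test, in 1 model of the 3 groups over all 9 libraries. The filter filterByExpr, at its minimum count of 10, left 22400 genes. The common biological coefficient of variation was 0.0284, with 6 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and fold changes are given on the log2 scale with standard errors. These were derived as the absolute fold change divided by the square root of the F statistic. They are approximate and can be too small where a group has few counts. CPM values are scaled by TMM, with a prior count of 2 where logs were taken. Tests of genes were two-sided. In a simulation on the same depths and spread, 64 to 67 genes each were planted at 1.5-fold, 2-fold and 4-fold. They were called at 78.8%, 89.4% and 100% for *thp1-5* against Col, 76.1%, 97.0% and 100% for *sac3bc* against Col and 87.7%, 95.4% and 100% for *thp1-5* against *sac3bc*. Of 21878, 21885 and 21876 unchanged genes, 12, 9 and 15 were called. Far fewer genes were changed in it than were called in the data, so these figures are not error rates of the calls below. Intervals of count ratios are exact binomial intervals and cover counting error alone.

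Gene lists fixed before the data were examined were tested with camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, and beside it with an estimated correlation and with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes. Adjusted p-values of lists are Benjamini-Hochberg values over the lists of a comparison. Lists with fewer than 3 tested members got no test. The 24 fixed lists of 417 entries, 7 of which were dropped because the reference names the locus otherwise, held TREX-2 subunits, nuclear pore and mRNA export factors, microRNA biogenesis factors, microRNA and trans-acting siRNA targets, *TAS* precursors, and genes of ethylene, flowering time, salicylic acid and immunity, jasmonate, abscisic acid with cold and drought, heat shock, nuclear photosynthesis, roots, flower organs, seeds, senescence, the clock, flavonoids, glucosinolates, phosphate starvation, iron, the cell cycle, auxin and DNA damage. Further lists followed a naming rule or locus type: chloroplast-encoded and mitochondria-encoded loci, cytosolic ribosomal proteins, histones, tRNAs, snRNAs and snoRNAs. The rule for cytosolic ribosomal proteins also let through genes of plastid ones, such as *RPS9* and *RPL15*. *MIR* loci were not analysed here. Some genes stand on more than 1 list, such as *AGO1* and *NUP1*.

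Named genes were chosen by a rule written before the data were examined. It takes the 4 genes *THP1*, *SAC3A*, *SAC3B* and *SAC3C*; per mutant against Col the 8 rising and 8 falling genes with the largest fold change among called genes with a symbol, a mean CPM of at least 1 and all 3 mutant libraries on the same side of all 3 Col libraries; the 5 rising and 5 falling between the mutants; the 6 rising and 6 falling in both; and per list up to 4 called members with the smallest adjusted p, or where fewer than 2 were called the 2 most abundant. *LURP1* in the mutants against Col, *NATA1*, *PRX52* and *CHLI1* were named after their values were seen. In all, 9959 loci share exonic bases with another locus, 7895 of them among the tested genes, and they take 34.8 to 36.5% of the counts; 92 loci with at least 90 counts in total have the same counts as another locus in every library. Among the named genes the shared part of the exonic bases was 68.1% for *FLC*, 35.8% for *SEP1*, 35.7% for *BHLH38*, 33.5% for *KN*, 33.1% for *HCHIB*, 31.4% for *AFB3*, 23.3% for *BGLU19*, 21.4% for *EBF2*, 20.5% for *WRKY53*, 16.2% for *CEN2*, 12.5% for *DELTA-VPE*, 11.2% for *RVE1* and 10.5% for *NUA*. *FLC*, the flowering repressor gene, was 1.60 ± 0.48 higher in *thp1-5* than in *sac3bc* (adjusted p = 0.00725, edgeR), a call lost without *sac3bc* replicate 2 (adjusted p = 0.0518).

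Alternatives set before the data were examined were RLE factors, no filter beyond 1 count, a filter at a mean CPM of 1, DESeq2 1.42.0, a fit of the 2 groups alone, the replicate number as a block, a log2 fold change of at least 1, a threshold of 0.01, each library left out in turn and the other list tests. Total counts in place of TMM factors, the removal of loci that share exonic bases, and a per-library correction for gene length and exonic GC content (a GC value for 99.4% of genes) were added after the data were seen. To judge the overlap of the mutants, all 9 libraries were simulated without any change from the Col means in 20 draws. The simulated Col libraries were shared by both comparisons. Families of genes with a common symbol prefix were tested by Fisher's exact test, and 1 family that passed it is not reported here.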

Results

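Polyadenylated RNA from 14-day-old *Arabidopsis thaliana* seedlings was sequenced in 9 libraries, 3 from the wild type Col, 3 labelled *thp1-5* and 3 labelled *sac3bc*. *THP1*, *SAC3B* and *SAC3C* encode subunits of TREX-2, a complex that couples transcription to mRNA export at the nuclear pore, and the series title names this complex and the pore together with microRNA biogenesis. The total count per library ran from 12.8 to 17.9 M. It averaged 14.7 ± 1.37 M in Col, 14.3 ± 2.09 M in *thp1-5* and 17.1 ± 0.960 M in *sac3bc* (SD, n = 3 each). Fully overlapping loci with the same counts, such as the abundant *LHB1B2* and AT2G08665, stand as separate loci. A share of the top loci can thus hold the same signal more than once. The 10 most abundant loci took 9.33 ± 0.101% of the counts in Col, 6.92 ± 0.106% in *thp1-5* and 6.20 ± 0.146% in *sac3bc* (SD, n = 3). Chloroplast-encoded loci took 0.845 ± 0.0642%, 0.569 ± 0.0195% and 0.583 ± 0.00760% of the counts in the same order (SD, n = 3). Replicates of a group differed by 1.45 to 1.92 times the variance of sampling noise, and libraries of different groups by 6.04 to 60.4 times. The first principal component held 72.2% of the variance. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

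The genes named by the genotypes were examined first, together with the paralog *SAC3A*. *THP1* (AT2G19560) stood at 12.6 ± 1.32 CPM in Col, 11.8 ± 0.787 in the libraries labelled *thp1-5* and 6.17 ± 1.03 in those labelled *sac3bc* (SD, n = 3 each). Its log2 fold change in *thp1-5* was −0.10 ± 0.11 (SE, adjusted p = 0.413, edgeR), so the transcript level does not mark the *thp1-5* genotype, while in *sac3bc* it fell by 1.03 on the log2 scale (SE 0.12, adjusted p = 2.92e-14, edgeR). *SAC3B* (AT3G06290) averaged 47.0 ± 0.270 CPM in Col, 33.2 ± 2.87 in *thp1-5* and 25.7 ± 2.38 in *sac3bc* (SD, n = 3), with log2 fold changes of −0.50 ± 0.06 and −0.87 ± 0.06. *SAC3C* (AT3G54380) averaged 15.2 ± 0.818, 13.4 ± 0.536 and 7.71 ± 0.214 CPM (SD, n = 3), a log2 fold change of −0.17 ± 0.10 in *thp1-5* that did not pass the test (adjusted p = 0.110, edgeR) and of −0.97 ± 0.10 in *sac3bc*. *SAC3A* (AT2G39340), which neither genotype label names, fell furthest of these genes. It went from 64.4 ± 4.34 CPM in Col to 38.7 ± 1.78 in *thp1-5* and 12.8 ± 0.949 in *sac3bc* (SD, n = 3), log2 fold changes of −0.73 ± 0.06 and −2.32 ± 0.06 (adjusted p = 7.1e-25 and 4.38e-69, edgeR). Transcript was thus left of *SAC3B* and *SAC3C* in the *sac3bc* libraries. The part of each gene hit by the mutation is not given in the sources used here, so counts over a whole gene check the labels only in part, and directions below are those of the libraries as labelled. With total counts in place of TMM factors the *THP1* and *SAC3C* values in *thp1-5* turned to 0.18 and 0.11, both still without a call. With the length and GC correction *SAC3C* was called lower in *thp1-5* (−0.22, adjusted p = 0.0453).

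**Figure D1:**
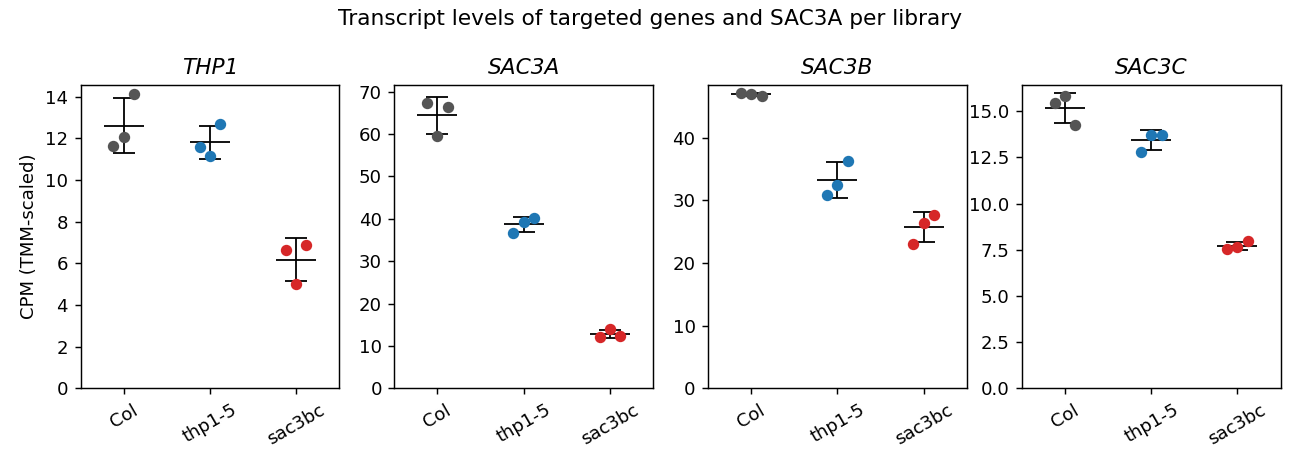
Each panel shows the TMM-scaled CPM (vertical axis, from 0) of *THP1*, *SAC3A*, *SAC3B* or *SAC3C* in the 3 Col, 3 *thp1-5* and 3 *sac3bc* libraries. Points are libraries, and black bars are the mean and SD; *THP1* averaged 12.6 CPM in Col and 11.8 in *thp1-5*, while *SAC3A* went from 64.4 in Col to 12.8 in *sac3bc*.

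The comparison of *thp1-5* with Col asked which transcripts differ in seedlings of this genotype. Genes of the iron deficiency response were among those with the largest rises: *BHLH100*, *BHLH39* and *BHLH38*, which encode transcription factors induced by low iron, rose by 5.21 ± 0.29, 4.0 ± 0.21 and 3.67 ± 0.20 on the log2 scale (SE, n = 3 per group). *HEC1*, a bHLH gene of gynoecium development, rose by 5.19 ± 0.26, *GPT2*, a plastid glucose-6-phosphate translocator, by 3.06 ± 0.17 and the receptor-like kinase gene *CRK30* by 3.01 ± 0.29. The histone acetyltransferase gene *HAC2* had 155 counts over the *thp1-5* libraries and 1 over the Col libraries, a ratio of 131 with an exact 95% counting interval of 23.1 to 5196. *QQS*, an orphan gene that affects starch content, went from 63.5 ± 1.89 to 1.54 ± 0.229 CPM (SD, n = 3), a log2 fold change of −5.34 ± 0.11. *CHAT*, *PCC1*, *BGLU45*, *DELTA-VPE*, the linker histone gene *HIS1-3* and the dark-induced gene *SEN1* changed by −4.10 ± 0.38, −3.90 ± 0.13, −3.73 ± 0.28, −3.66 ± 0.33, −3.50 ± 0.07 and −3.42 ± 0.06, each with an adjusted p of 1.96e-18 or lower by edgeR. *MYB15* rose by 3.15 ± 0.61.

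In all, 14297 of the 22400 genes tested were called in *thp1-5* (63.8%, adjusted p under 0.05, edgeR), 7180 higher and 7117 lower, and 1109 of the higher and 1014 of the lower ones changed at least 2-fold. TMM scaling sets the balance of directions: with total counts alone the median of all genes shifted by 0.29 on the log2 scale, 16152 genes were called and 77.6% of them were higher, against 50.2% with TMM. Of the calls, 10794 kept their sign under total counts, 541 had the opposite sign and 2962 were lost, while 2091 of the 2123 genes changed at least 2-fold kept theirs.

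Transcripts for photosynthesis were lower in *thp1-5*. Of 21 nuclear-encoded photosynthesis genes, 20 fell and 0 rose (median −0.53; 21 fell when adjusted over the list alone), although with total counts 16 were lower and 3 higher. *LHCB1.3* changed by −0.88 ± 0.02, *LHCB1.2* by −0.85 ± 0.02 and the photosystem I subunit *PSAF* by −0.85 ± 0.02. *LHCB1.2* and *LHCB1.3* have near-identical copies, and how reads were divided between them is not given in the sources used here. The list stood below other genes by camera (adjusted p = 5.83e-30; adjusted p = 0.0727 with an estimated correlation). Of 105 chloroplast-encoded loci, 78 fell and 0 rose (median −0.77, adjusted p = 5.13e-11; adjusted p = 0.106 with an estimated correlation). With total counts 48 were lower and 1 higher (median −0.49). ATCG00440 and ATCG00430, which encode subunits of the plastid NDH complex, changed by −1.61 ± 0.06 and −1.10 ± 0.03. These transcripts were measured in RNA selected for poly(A), which chloroplast transcripts mostly lack.

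Several other groups rose in *thp1-5*. All 11 tested genes of flavonoid and anthocyanin synthesis rose (median 1.49, adjusted p = 1.6e-05 by camera; adjusted p = 0.0727 with an estimated correlation). The anthocyanin enzyme genes *LDOX* and *DFR* rose by 2.53 ± 0.17 and 2.38 ± 0.17, and *CHS*, which encodes the first committed enzyme of the pathway, by 1.14 ± 0.04. Of 13 cell cycle genes, 12 rose and 0 fell (median 0.71, adjusted p = 0.000108; adjusted p = 0.0727 with an estimated correlation), including the cyclins *CYCA1;1* (1.32 ± 0.09) and *CYCB1;2* (1.15 ± 0.08). Of 11 iron homeostasis genes, 8 rose and 2 fell (median 1.04, adjusted p = 0.00346; adjusted p = 0.0727 with an estimated correlation). *BTS*, which encodes an iron-binding ubiquitin ligase, rose by 1.04 ± 0.03. Of 12 phosphate starvation genes, 9 rose and 1 fell (median 0.77, adjusted p = 0.01; adjusted p = 0.0727 with an estimated correlation), and with total counts 12 were higher. *SPX1* changed by 1.62 ± 0.06, *MGD3* by 1.55 ± 0.27 and the acid phosphatase *PAP17* by 0.68 ± 0.05. Of 15 ethylene genes, 10 rose and 3 fell (median 0.43, adjusted p = 0.0149; adjusted p = 0.0727 with an estimated correlation). When adjusted over the list alone 4 fell. The F-box gene *EBF2* rose by 0.99 ± 0.03 and the transcription factor gene *EIN3*, whose protein *EBF2* targets, changed by −0.47 ± 0.03. Of 21 histone genes, 14 rose and 3 fell (median 0.26, adjusted p = 0.00848; adjusted p = 0.0727 with an estimated correlation). *HTR11* changed by 2.17 ± 0.22 and *HTA9* by −0.50 ± 0.04. Of 10 auxin response genes, 7 rose and 2 fell (median 0.75, adjusted p = 0.00848; adjusted p = 0.105 with an estimated correlation). *IAA1* changed by 1.12 ± 0.07 and *IAA2* by 0.88 ± 0.04. Of 8 DNA damage response genes, 5 rose and 0 fell (median 0.57, adjusted p = 0.0262; adjusted p = 0.0965 with an estimated correlation). *GMI1* changed by 2.11 ± 0.13, *BRCA1* by 1.01 ± 0.13 and *TSO2* by 0.79 ± 0.05. The ethylene and DNA damage calls were lost without loci that share exonic bases (adjusted p = 0.0638 and 0.228), and the latter also with total counts (adjusted p = 0.0709).

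Genes of water and cold stress, seeds and flowering were lower in *thp1-5*. Of 14 genes responding to abscisic acid, cold or drought, 11 fell and 2 rose (median −0.76, adjusted p = 1.6e-05; adjusted p = 0.0727 with an estimated correlation), and with total counts 9 were lower and 4 higher. The dehydrin gene *RAB18* changed by −1.97 ± 0.05 and *COR15A* by −1.73 ± 0.03. Of 6 seed storage and late embryogenesis genes, 5 fell and 0 rose (median −2.02, adjusted p = 0.00848; adjusted p = 0.0727 with an estimated correlation). The oleosin gene *OLEO2* changed by −2.45 ± 0.24 and the cruciferin genes *CRA1* by −2.2 ± 0.08 and *CRU3* by −1.35 ± 0.12. Of 13 flowering time genes, 8 fell and 1 rose (median −0.25, but 0.03 with total counts, under which 6 were lower and 3 higher; adjusted p = 0.0214; adjusted p = 0.0842 with an estimated correlation). The floral promoters *FUL* and *SOC1* changed by −2.48 ± 0.21 and −1.65 ± 0.04. The list also holds floral repressors such as *FLC*, so its direction as a list is not a direction of flowering.

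For the subject named in the title, 86 genes targeted by microRNAs or trans-acting siRNAs were tested. In *thp1-5*, 41 rose and 22 fell, and the median was 0.18 (57 higher and 9 lower with total counts). *GRF3*, a target of miR396, rose by 1.21 ± 0.06 and the auxin receptor gene *AFB3*, a target of miR393, by 1.15 ± 0.04. The miR395 targets *SULTR2;1* and *APS4*, a sulfate transporter and an ATP sulfurylase, changed by −1.18 ± 0.03 and −1.16 ± 0.04. Camera placed the list above other genes (adjusted p = 0.0406). That call was lost with an estimated correlation (adjusted p = 0.0727), without loci that share exonic bases (adjusted p = 0.194) and after a length and GC correction (adjusted p = 0.122), in a range of 0.0280 to 0.194 over the alternatives that use camera. The test fry, which compares the list with no other genes, gave an adjusted p of 4.35e-05. Of 32 microRNA biogenesis factors, 8 rose and 8 fell, with no shift as a list (median 0.00, mean −0.01, direction of the test down, adjusted p = 0.823; with total counts 24 were higher and 4 lower). The slicer gene *AGO1* changed by −0.44 ± 0.03, *MAC3B* by −0.54 ± 0.04, the uridylyltransferase gene *URT1* by −0.46 ± 0.05 and the RNA-binding protein gene *GRP7* by −0.51 ± 0.02. Of 31 nuclear pore and mRNA export factors, 17 rose and 5 fell (median 0.19, adjusted p = 0.00848; adjusted p = 0.0727 with an estimated correlation, and 0.104 without loci that share exonic bases), and with total counts 26 were higher and 2 lower. The export helicase genes *UAP56B* and *UAP56A* rose by 1.07 ± 0.03 and 1.04 ± 0.03, and as near-identical neighbours they may share reads. *ALY3* rose by 0.53 ± 0.04. Of 9 TREX-2 subunits, 1 rose (*NUP1*, by 0.40 ± 0.05) and 5 fell, and the list was not called (median −0.15, but 0.13 with total counts, under which 3 were higher and 3 lower; adjusted p = 0.375). Among them the centrin gene *CEN2* changed by −0.86 ± 0.12. Of 6 *TAS* precursors 0 rose and 1 fell (median −0.02, but 0.26 with total counts, under which 3 were higher and 1 lower; adjusted p = 0.900). *TAS3* changed by −0.58 ± 0.12. *MIR* loci were not analysed here.

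The remaining lists were not called in *thp1-5* with the settings used throughout. Of 17 salicylic acid and immune genes, 6 rose and 4 fell (median −0.03, mean 0.06, direction of the test up, adjusted p = 0.385; the median was 0.26 with total counts). *WRKY18* changed by 1.42 ± 0.14, *WRKY53* by 1.00 ± 0.09 and *WRKY33* by 0.89 ± 0.06. *PR1* had 3 counts against 40 in Col, a ratio of 0.0632 (exact 95% counting interval 0.0125 to 0.199). Of 12 jasmonate genes, 5 rose and 5 fell (median −0.04, but 0.25 with total counts, under which 5 were higher and 3 lower; adjusted p = 0.375). The storage protein genes *VSP1* and *VSP2* changed by −3.13 ± 0.05 and −2.58 ± 0.03. Of 9 root markers, 7 rose and 1 fell (median 0.72, adjusted p = 0.198), and the list was called higher without loci that share exonic bases, which left 6 members (adjusted p = 0.0149). The root hair genes *LRX1* and *PRP3* rose by 0.98 ± 0.11 and 0.85 ± 0.06, but the abundant *PYK10*, a root beta-glucosidase, changed by −1.10 ± 0.02. The test fry gave the direction down (adjusted p = 1.52e-05). Of 9 senescence genes, 2 rose and 4 fell (median −0.37, adjusted p = 0.0692, and 0.0463 with total counts). *NAP* changed by −1.99 ± 0.15 and *WRKY6* by 1.01 ± 0.07. Of 12 clock genes, 3 rose and 6 fell (median −0.15, but 0.14 with total counts, under which 7 were higher and 3 lower; adjusted p = 0.375). *PRR9* changed by 1.05 ± 0.05 and *PRR7* by −0.89 ± 0.03. Of 16 glucosinolate synthesis genes, 11 rose and 4 fell (median 0.21, adjusted p = 0.0820, and 0.0019 with total counts, under which 14 were higher and 1 lower). *SOT16* changed by 0.57 ± 0.04 and *MAM1* by −0.37 ± 0.03. Of 43 cytosolic ribosomal protein genes, 13 rose and 14 fell (median −0.01, direction of the test down, adjusted p = 0.761), but with total counts 33 were higher and 4 lower and the list stood above other genes (median 0.28, adjusted p = 0.00659). *RPS9* and *RPL15*, at −0.51 ± 0.03 and −0.37 ± 0.03, encode plastid ribosomal proteins that the naming rule of this list let through. Of 5 heat shock genes 1 rose (adjusted p = 0.480), and with total counts 4 were higher and 0 lower. *HSP70* stood at 0.06 ± 0.07 and *HSP90.1* at −0.23 ± 0.11, both without a call (adjusted p = 0.434 and 0.0561, edgeR). *HSP90.1* was called lower without Col replicate 3 (adjusted p = 0.0364), *thp1-5* replicate 1 (0.0290) or *thp1-5* replicate 3 (0.0110), without loci that share exonic bases (0.0439) and with the length and GC correction (0.0104), while with total counts it stood at 0.056 (0.652). *HSP70* was called higher with total counts (0.35, adjusted p = 2.3e-06). All 3 tested flower organ identity genes fell, *SEP1* by −1.15 ± 0.32, but the list was not called (adjusted p = 0.480). Of 20 mitochondria-encoded loci 1 rose and 7 fell (adjusted p = 0.480), and with total counts 4 were higher and 4 lower. ATMG00640 changed by −2.41 ± 0.40. Of 97 snoRNA loci 21 rose and 35 fell (median −0.32, adjusted p = 0.596). With total counts 28 were higher and 19 lower, and the list, at a median of −0.039, stood below other genes, which shifted up as a whole (adjusted p = 0.00513). AT1G03935 changed by −4.24 ± 0.51. Without loci that share exonic bases 56 snoRNA loci were tested. As the RNA was selected for poly(A), counts at snoRNA, snRNA and tRNA loci, here and below, may not measure the mature RNAs. Of 16 snRNA loci 2 rose and 3 fell (median 0.02, mean −0.05, direction of the test up, adjusted p = 0.900; 5 higher and 1 lower with total counts), and of 4 tRNA loci 1 rose and 2 fell (adjusted p = 0.766). For each fixed list the counts adjusted over the list alone were those over all genes, apart from the photosynthesis and ethylene lists.

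**Figure D2:**
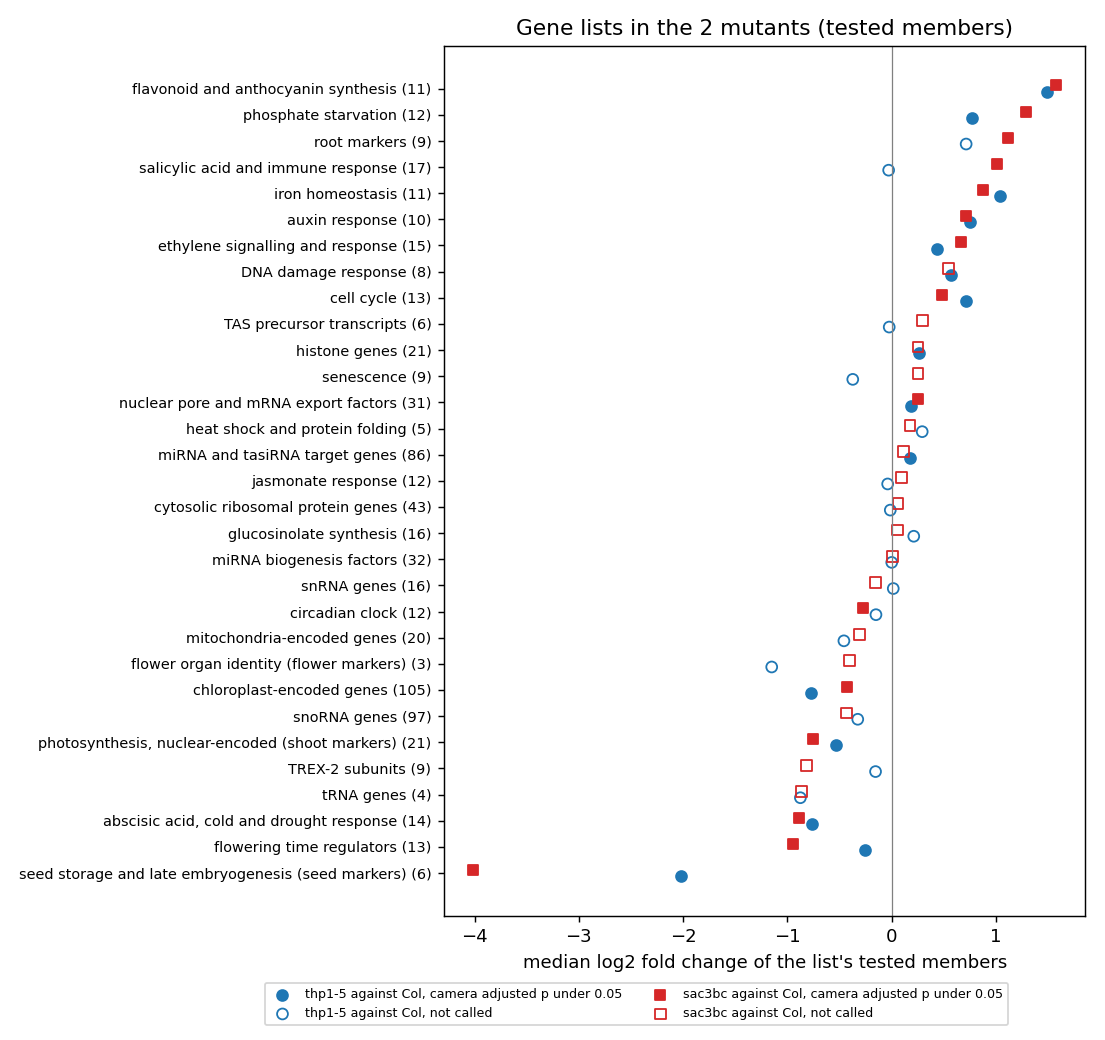
Median log2 fold change of the tested members of each gene list (horizontal axis; list names with their numbers of tested members on the vertical axis) in *thp1-5* (blue circles) and *sac3bc* (red squares) against Col. Filled symbols passed camera at an adjusted p under 0.05 and open ones did not; seed genes lie lowest (−2.02 and −4.01) and flavonoid genes highest (1.49 and 1.58), and total counts in place of TMM factors shift all genes by a median of 0.29 and 0.34, which among the called lists turns those of flowering time in *thp1-5* and of the clock in *sac3bc* above 0.

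The comparison of *sac3bc* with Col asked the same for libraries labelled with the *SAC3B* and *SAC3C* genotype. Seed transcripts were among those that fell most: the cruciferin genes *CRU3* and *CRA1* changed by −5.90 ± 0.22 and −4.97 ± 0.11, the seed peroxiredoxin gene *PER1* by −4.74 ± 0.30 and *OLEO2* by −4.01 ± 0.28 (SE, n = 3 per group). *QQS* changed by −5.04 ± 0.10, *DELTA-VPE* by −4.48 ± 0.35, *BGLU19* by −4.21 ± 0.16 and *CYP76G1* by −3.83 ± 0.40. *BHLH100*, *HEC1*, *BHLH39* and *BHLH38* rose by 5.54 ± 0.27, 5.04 ± 0.26, 4.67 ± 0.19 and 4.34 ± 0.18. *GPT2* rose by 4.33 ± 0.14, *MYB15* by 4.15 ± 0.51 and the phosphatase gene *PS2*, induced by phosphate starvation, by 3.96 ± 0.14. *HAC2* had 118 counts against 1 in Col, a ratio of 80.5 (exact 95% counting interval 14.2 to 3206).

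In *sac3bc*, 15232 genes were called (68% of those tested, edgeR), 7829 higher and 7403 lower, with 1569 and 1248 changed at least 2-fold. With total counts the median of all genes shifted by 0.34, 17261 genes were called and 78.9% of them were higher, against 51.4% with TMM. Of the calls 11465 kept their sign, 906 had the opposite sign and 2861 were lost, while 2777 of 2817 changed at least 2-fold kept theirs.

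Defence, phosphate and ethylene genes rose in *sac3bc* with calls that were kept with an estimated correlation (adjusted p = 0.0454 for each of these lists). Of 17 salicylic acid and immune genes, 13 rose and 1 fell (14 rose when adjusted over the list alone; median 1.01, adjusted p = 0.000326). *PR2* changed by 2.46 ± 0.15, the camalexin enzyme *PAD3* by 2.2 ± 0.16, *WRKY18* by 1.82 ± 0.13 and *WRKY33* by 1.36 ± 0.06. *PR1* rose from 40 to 319 counts (2.43 ± 0.23). Of 12 phosphate starvation genes, 11 rose and 0 fell (median 1.29, adjusted p = 7.4e-05). *MGD3* changed by 2.70 ± 0.22, *SPX1* by 2.33 ± 0.05 and *PAP17* by 1.35 ± 0.05. Of 15 ethylene genes, 11 rose and 1 fell (median 0.66, adjusted p = 0.000411). *EBF2* rose by 1.36 ± 0.03, while *EIN3* changed by −0.41 ± 0.03. Flavonoid synthesis behaved likewise, with 10 of 11 genes higher and 0 lower (median 1.58, adjusted p = 3.22e-05; adjusted p = 0.0454 with an estimated correlation). *DFR* changed by 2.76 ± 0.16, *LDOX* by 2.62 ± 0.16 and *CHS* by 1.34 ± 0.04.

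All 21 nuclear photosynthesis genes fell in *sac3bc* (median −0.76, adjusted p = 1.82e-30; adjusted p = 0.0688 with an estimated correlation), although with total counts 20 were lower and 1 higher. *LHCB1.3* changed by −1.10 ± 0.02, *PSAF* by −1.05 ± 0.02 and *LHCB1.2* by −1.04 ± 0.02. Of 105 chloroplast-encoded loci, 55 fell and 7 rose (median −0.43, adjusted p = 3.22e-05; adjusted p = 0.259 with an estimated correlation; with total counts 35 were lower and 20 higher). ATCG00440 changed by −1.53 ± 0.05 and ATCG00430 by −1.12 ± 0.03. Of 14 genes responding to abscisic acid, cold or drought, 11 fell and 2 rose (median −0.89, adjusted p = 0.000153; adjusted p = 0.0688 with an estimated correlation; with total counts 9 lower and 5 higher). *RAB18* changed by −2.30 ± 0.05 and *COR15A* by −1.80 ± 0.03. All 6 seed genes fell (median −4.01, adjusted p = 0.0015; adjusted p = 0.0584 with an estimated correlation). Of 13 flowering time genes, 11 fell and 1 rose (median −0.94, adjusted p = 0.00456; adjusted p = 0.0688 with an estimated correlation; with total counts 7 lower and 3 higher). *FUL* changed by −2.19 ± 0.19 and *SOC1* by −1.79 ± 0.04. Of 12 clock genes, 9 fell and 1 rose (median −0.28, but 0.06 with total counts, under which 6 were higher and 3 lower; adjusted p = 0.0217; adjusted p = 0.0853 with an estimated correlation, and 0.143 with total counts). *PRR7* changed by −1.09 ± 0.03 and *PRR9* by 0.96 ± 0.05.

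Of 11 iron homeostasis genes, 8 rose and 1 fell in *sac3bc* (median 0.87, adjusted p = 0.0015; adjusted p = 0.0584 with an estimated correlation). *BTS* changed by 0.87 ± 0.03. Of 10 auxin response genes, 8 rose and 0 fell (median 0.71, adjusted p = 0.00289; adjusted p = 0.0853 with an estimated correlation). *IAA1* changed by 1.01 ± 0.07 and *IAA2* by 0.73 ± 0.03. Of 13 cell cycle genes 11 rose and 1 fell (median 0.48, adjusted p = 0.00734; adjusted p = 0.0853 with an estimated correlation). *CYCA1;1* changed by 1.16 ± 0.09 and *CYCB1;2* by 0.74 ± 0.08. Of 9 root markers, 8 rose and 1 fell (median 1.12, adjusted p = 0.0191; adjusted p = 0.0945 with an estimated correlation, and 0.125 with total counts). *LRX1* changed by 1.64 ± 0.10 and *PRP3* by 1.52 ± 0.06, but *PYK10* changed by −1.13 ± 0.02 and fry gave the direction down (adjusted p = 0.00192). Of 31 nuclear pore and mRNA export factors, 18 rose and 6 fell (median 0.25, adjusted p = 0.0112; adjusted p = 0.0802 with an estimated correlation, and 0.0883 without loci that share exonic bases; with total counts 28 higher and 1 lower). *UAP56B* changed by 1.22 ± 0.03, *UAP56A* by 1.11 ± 0.03 and *ALY3* by 0.63 ± 0.03.

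The microRNA and trans-acting siRNA targets were not called as a list in *sac3bc* (median 0.11, adjusted p = 0.307, range 0.157 to 0.644 over the alternatives that use camera). Of the 86 genes, 35 rose and 21 fell (63 higher and 10 lower with total counts). *AFB2* changed by 1.07 ± 0.05, *AFB3* by 1.06 ± 0.04, *SULTR2;1* by −1.67 ± 0.03 and *APS4* by −1.56 ± 0.04. Of 32 microRNA biogenesis factors, 9 rose and 10 fell (median 0.01, mean −0.04, direction of the test down, adjusted p = 0.561; with total counts 24 higher and 5 lower). *AGO1* changed by −0.53 ± 0.03, *MAC3B* by −0.56 ± 0.04, *URT1* by −0.46 ± 0.04 and *GRP7* by −0.58 ± 0.02. Of 6 *TAS* precursors, 3 rose and 1 fell (median 0.29, adjusted p = 0.751). *TAS2*, *TAS1C* and *TAS1A* rose by 0.30 ± 0.10, 0.33 ± 0.12 and 0.28 ± 0.13, and *TAS3* changed by −0.72 ± 0.12. Each of the 3 calls was lost in at least 1 fit with 1 library left out. The call of *TAS2* was lost without *sac3bc* replicate 1 (0.23, adjusted p = 0.0532). That of *TAS1C* was lost without Col replicate 2 (adjusted p = 0.123), without *sac3bc* replicate 2 (0.0558) and with DESeq2 (0.0768). That of *TAS1A* was lost without Col replicate 1 (adjusted p = 0.195), Col replicate 3 (0.0892), *sac3bc* replicate 1 (0.0645) or *sac3bc* replicate 3 (0.134). It was also lost with RLE factors (0.0601), no filter (0.0519), DESeq2 (0.152), a fit of the 2 groups alone (0.0527) and without loci that share exonic bases (0.0634). Of 9 TREX-2 subunits, 1 rose (*NUP1*, by 0.43 ± 0.05) and 6 fell (median −0.81, adjusted p = 0.0538). The list was called without Col replicate 3 (adjusted p = 0.0408), with total counts (adjusted p = 0.0430) and without loci that share exonic bases (adjusted p = 0.0277). It holds *SAC3B* and *SAC3C*, which the label names, so its values are not independent of the genotype.

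Of 21 histone genes, 13 rose and 4 fell in *sac3bc* (median 0.25, adjusted p = 0.0538). The list was called without *sac3bc* replicate 2 (adjusted p = 0.0456), with total counts (0.0262), without loci that share exonic bases (0.0270) and with the length and GC correction (0.0225). *HTR11* changed by 2.43 ± 0.21 and *HTA9* by −0.57 ± 0.04. Of 8 DNA damage genes 4 rose and 0 fell (median 0.55, adjusted p = 0.0808), and with total counts 7 were higher and 0 lower (median 0.88). *GMI1* changed by 2.11 ± 0.13. Of 12 jasmonate genes 5 rose and 5 fell (median 0.10, mean −0.15, direction of the test down, adjusted p = 0.553), but with total counts 9 were higher and 3 lower (median 0.43). *VSP1* changed by −3.03 ± 0.05 and *VSP2* by −2.24 ± 0.03. Of 9 senescence genes 5 rose and 4 fell (median 0.25, mean −0.28, direction of the test down, adjusted p = 0.561). Of 16 glucosinolate genes 7 rose and 5 fell (12 higher and 2 lower with total counts; adjusted p = 0.574; fry gave the direction down, adjusted p = 0.978). *SOT16* changed by 0.70 ± 0.04, *CYP83B1* by 0.69 ± 0.03 and *MAM1* by −0.75 ± 0.03. Of the 43 genes on the list of cytosolic ribosomal proteins, which holds plastid ones as well, 22 rose and 11 fell (adjusted p = 0.294, and 0.000594 with total counts, under which 37 were higher and 5 lower). Of 5 heat shock genes 3 rose and 0 fell (adjusted p = 0.307), and with total counts 5 were higher. The endoplasmic reticulum chaperone gene *BIP3* changed by 2.37 ± 0.43. Of 3 flower organ identity genes 0 rose and 1 fell (adjusted p = 0.645), of 20 mitochondria-encoded loci 4 rose and 8 fell (median −0.31, but 0.03 with total counts, under which 6 were higher and 5 lower; adjusted p = 0.882), and of 4 tRNA loci 0 rose and 3 fell (adjusted p = 0.561). Of 16 snRNA loci 1 rose and 2 fell (median −0.16, but 0.18 with total counts, under which 4 were higher and 2 lower; adjusted p = 0.882), and of 97 snoRNA loci 20 rose and 40 fell (median −0.43, adjusted p = 0.553). With total counts 32 snoRNA loci were higher and 21 lower, and the list, at a median of −0.093, stood below other genes (adjusted p = 0.00203). For the fixed lists, the counts adjusted over the list alone differed from those over all genes in the immune list alone.

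The overlap of the comparisons asked whether the same transcripts changed in both genotypes. In both mutants 12584 genes were called in the same direction (6281 higher, 6303 lower) and 101 in opposite directions. Genes that rose at least 2-fold in both included *HAC2*, *BHLH100*, *HEC1*, *BHLH39*, *BHLH38*, *MYB15* and *GPT2*. *QQS*, *CHAT*, *BGLU45*, *DELTA-VPE*, *HIS1-3* and *SEN1* fell in both. In *sac3bc*, *CHAT* changed by −3.79 ± 0.34, *BGLU45* by −3.62 ± 0.26, *HIS1-3* by −3.72 ± 0.07 and *SEN1* by −3.49 ± 0.05. Lists that do not depend on each other would share 2509 higher and 2352 lower calls. Across genes, which are not independent replicates, the fold changes correlated at 0.92 (Spearman 0.919), with the same sign in 88.7% of genes. Libraries simulated without change from the Col means, with the simulated Col libraries shared, gave a mean correlation of 0.559, the same sign in 68.5% and 0.15 shared calls over 20 draws. The covariance was 0.463 against a simulated 0.0122, a difference of 0.451. The 3 Col libraries cannot be split into 2 sets of at least 2 libraries, so part of the excess of the correlation and of the shared calls may come from the shared controls. The difference of the covariances leaves out only what the random spread of shared controls adds. A shift of the Col samples as a whole would stay in it. The sources used here do not say whether Col was grown together with the mutants, and a difference in growth or handling of the Col seedlings would give shared calls as well. With total counts 14825 genes were called alike in both, 79.5% of them higher, against 49.9% with TMM.

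**Figure D3:**
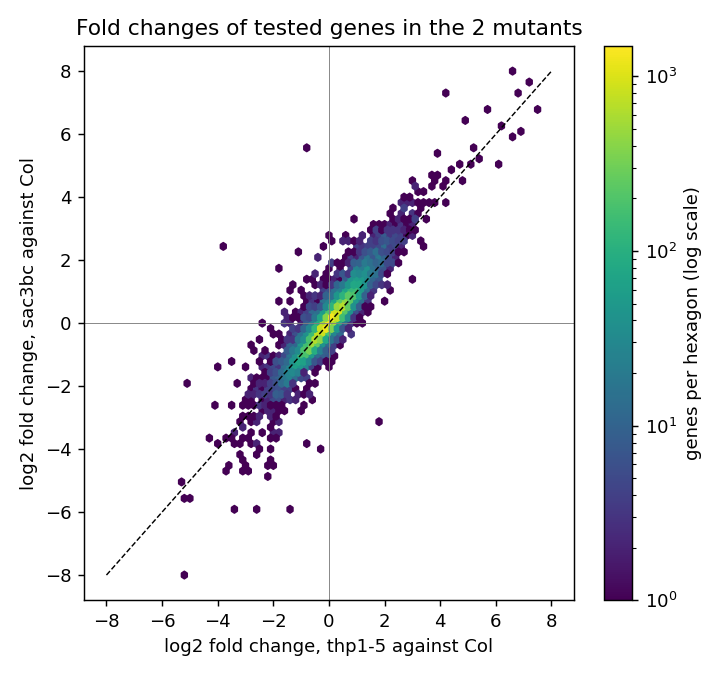
Log2 fold change of each of the 22400 tested genes in *thp1-5* (horizontal axis) and *sac3bc* (vertical axis) against Col, with the number of genes per hexagon on a log colour scale and the dashed line marking equal change. Most genes lie near the line (correlation 0.92 across genes, with the 3 Col libraries shared), and *PR1*, at −3.83 and 2.43, lies far from it.

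**Figure D4:**
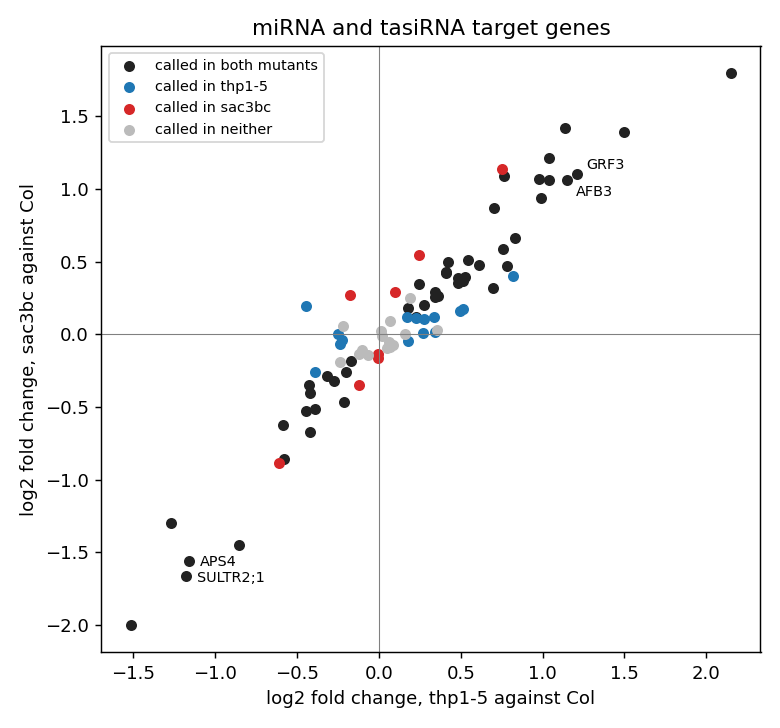
Log2 fold changes of the 86 microRNA and trans-acting siRNA target genes in *thp1-5* (horizontal axis) and *sac3bc* (vertical axis) against Col, coloured by the comparison in which each was called. In *thp1-5* 41 were called higher and 22 lower, in *sac3bc* 35 and 21 (57 and 9, and 63 and 10, with total counts); *SULTR2;1* and *APS4* lie far below 0 in both.

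The direct comparison of *thp1-5* with *sac3bc* tested the difference between the genotypes. Defence transcripts were lower in *thp1-5* than in *sac3bc*. *PR1* had 3 counts over the *thp1-5* libraries and 319 over those of *sac3bc*, a ratio of 0.0116 (exact 95% counting interval 0.00239 to 0.0343). *LURP1*, the wall-associated kinase gene *WAK3* and the glucanase gene *PR2* changed by −3.48 ± 0.16, −2.81 ± 0.31 and −2.68 ± 0.15 (SE, n = 3 per group). *PCR1*, not counted here as a defence gene, changed by −3.44 ± 0.38. Of 17 salicylic acid and immune genes 15 were lower and 0 higher in *thp1-5* (median −0.59, adjusted p = 1.87e-12, and 0.00625 with an estimated correlation). *WRKY70* changed by −1.50 ± 0.11 and *WRKY33* by −0.46 ± 0.05. Seed transcripts were higher in *thp1-5*: *CRU3* by 4.55 ± 0.26, *CRA1* by 2.77 ± 0.15 and *M17* by 1.78 ± 0.27. Of 6 seed genes 5 were higher and 0 lower (median 2.19, adjusted p = 6.99e-06, and 0.0192 with an estimated correlation). *BGLU19* was higher by 1.58 ± 0.22 and *SAC3A* by 1.59 ± 0.07, and *THP1*, *SAC3C* and *SAC3B* by 0.93 ± 0.12, 0.80 ± 0.10 and 0.36 ± 0.06.

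Between the mutants 5150 genes were called (edgeR), 2703 higher and 2447 lower in *thp1-5*, and 233 changed at least 2-fold, 50 higher and 183 lower. With total counts 5468 were called, 32.3% of them higher against 52.5% with TMM. Of the calls 4212 kept their sign, 0 had the opposite sign and 938 were lost. With DESeq2 3290 genes were called, 60.3% of them higher.

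Photosynthesis genes were higher in *thp1-5* than in *sac3bc*, 20 of 21 over all genes and 21 when adjusted over the list alone (median 0.19, adjusted p = 1.12e-57, and 0.0239 with an estimated correlation). *RCA* changed by 0.28 ± 0.02 and *LHCB1.3* by 0.22 ± 0.02. Of 12 phosphate starvation genes 10 were lower and 0 higher (median −0.57, adjusted p = 2.15e-10, and 0.00625 with an estimated correlation). The non-coding RNA gene *AT4* changed by −0.93 ± 0.10, *SPX1* by −0.71 ± 0.04 and *PAP17* by −0.67 ± 0.04. Of 15 ethylene genes 7 were lower and 0 higher (8 lower when adjusted over the list alone; median −0.14, adjusted p = 3.33e-06, and 0.0172 with an estimated correlation). *ORA59* changed by −1.03 ± 0.18, *HCHIB* by −0.84 ± 0.07 and *EBF2* by −0.37 ± 0.03. Of 9 root markers 6 were lower and 0 higher (median −0.41, adjusted p = 2.75e-05, and 0.0239 with an estimated correlation). *PRP3* changed by −0.67 ± 0.05 and *LRX1* by −0.66 ± 0.08. Of 12 clock genes 6 were higher and 0 lower (median 0.14, adjusted p = 0.000193, and 0.0239 with an estimated correlation). *RVE1* changed by 0.79 ± 0.08 and *PRR5* by 0.42 ± 0.03. Of the 9 TREX-2 subunits 4 were higher and 0 lower (median 0.08, adjusted p = 0.000887, and 0.0479 with an estimated correlation), the 4 genes *THP1*, *SAC3A*, *SAC3B* and *SAC3C*. As the genotype labels name *THP1*, *SAC3B* and *SAC3C*, this list call is not independent of the genotypes. Of 86 microRNA and trans-acting siRNA targets 20 were higher and 6 lower (24 and 7 when adjusted over the list alone; 12 and 9 with total counts; median 0.09, adjusted p = 0.0116, and 0.0479 with an estimated correlation). *SULTR2;1* was higher by 0.49 ± 0.03 and *APS4* by 0.40 ± 0.04.

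For 5 further lists the call between the mutants was lost with an estimated correlation. Of 105 chloroplast-encoded loci 29 were lower and 1 higher in *thp1-5* (median −0.14, adjusted p = 2.75e-05; adjusted p = 0.273 with an estimated correlation). ATCG01100 changed by −1.48 ± 0.13 and ATCG00120 by −1.20 ± 0.10. Of 43 cytosolic ribosomal protein genes 20 were lower and 6 higher (median −0.09, adjusted p = 0.000152; adjusted p = 0.205 with an estimated correlation, and 0.0835 after the length and GC correction). This list holds plastid ribosomal proteins as well. Its member *RPL3B* changed by −0.43 ± 0.07. Of 13 cell cycle genes 5 were higher and 0 lower (median 0.14, adjusted p = 0.00246; adjusted p = 0.0645 with an estimated correlation, and 0.0992 without loci that share exonic bases). *KN* and *CYCB1;2* changed by 0.41 ± 0.05 and 0.41 ± 0.06. Of 9 senescence genes 6 were lower and 1 higher (median −0.22, adjusted p = 0.00682; adjusted p = 0.140 with an estimated correlation). *SAG13* changed by −2.23 ± 0.31 and *ORE1* by −0.45 ± 0.09. Of 16 glucosinolate genes 8 were higher and 3 lower (median 0.09, adjusted p = 0.00743; adjusted p = 0.0599 with an estimated correlation).

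The other lists were not called between the mutants with the settings used throughout. Of 11 flavonoid genes 4 were lower and 0 higher (5 lower when adjusted over the list alone; adjusted p = 0.0512, and 0.0430 and 0.0491 without *sac3bc* replicate 1 or 2). *CHS* changed by −0.20 ± 0.04. Of 12 jasmonate genes 4 were lower and 2 higher (adjusted p = 0.0512, with 0.0319 to 0.0494 in the 5 cases in which leaving out Col replicate 1, *thp1-5* replicate 1 or 3 or *sac3bc* replicate 1 or 2 made the call). It was also called with a mean CPM of 1 (adjusted p = 0.0491), with total counts (0.0402) and without loci that share exonic bases (0.0261). Of 13 flowering time genes 4 were higher and 0 lower (5 higher when adjusted over the list alone; adjusted p = 0.0973), and of 11 iron genes 4 were lower and 1 higher (median 0.05, mean −0.12, direction of the test down, adjusted p = 0.241). *BHLH39* changed by −0.67 ± 0.10. Of 14 genes responding to abscisic acid, cold or drought 3 were lower and 1 higher (median −0.01, mean 0.02, direction of the test down, adjusted p = 0.693). Of 31 nuclear pore and mRNA export factors 4 were higher and 3 lower (adjusted p = 0.516), but with total counts 2 were higher and 6 lower. *NUA* changed by 0.21 ± 0.03. Of 32 microRNA biogenesis factors 5 were higher and 1 lower (5 and 0 when adjusted over the list alone; median 0.03, but −0.02 with total counts; adjusted p = 0.241). Of 6 *TAS* precursors 0 were higher and 1 lower (adjusted p = 0.353). *TAS2* changed by −0.39 ± 0.10. Of 10 auxin genes 2 were higher and 4 lower (adjusted p = 0.516), of 21 histone genes 4 were higher and 0 lower (adjusted p = 0.241, and 0.0240 with the length and GC correction), and of 5 heat shock genes 0 were higher and 1 lower (adjusted p = 0.345). The 8 DNA damage genes, 3 flower organ identity genes and 4 tRNA loci had medians of 0.08, −0.48 and 0.36 (adjusted p = 0.516, 0.660 and 0.516). Of the flower genes 1 was higher and 2 were lower when adjusted over the list alone, and no call was made over all genes. Of 20 mitochondria-encoded loci 0 were higher and 4 lower (adjusted p = 0.124), of 16 snRNA loci 1 was higher and 0 lower (median −0.00, mean 0.09, direction of the test up, adjusted p = 0.660), and of 97 snoRNA loci 2 were higher and 1 lower (adjusted p = 0.860). For the other fixed lists the counts adjusted over the list alone were those over all genes.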

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

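The tests of photosynthesis genes and of *CHLI1*, the test of another genotype for *SAC3A*, and the counts of splits in single comparisons were chosen after the results were seen, while the search for shared sequence of *SAC3A* and the splits for both mutants were set before. The 2 mutants moved some genes apart: 101 genes were called in opposite directions against Col, 42 of them higher and 59 lower in *thp1-5*. All 101 were also called between the mutants. That comparison is the difference of the 2 against Col in the same fit, so it adds little separate support. Directions against Col depend on the TMM scaling, and these genes were not counted again with total counts. *PR1*, a marker of salicylic acid response, differed by −6.26 ± 0.39 between *thp1-5* and *sac3bc* (adjusted p = 1.08e-30, edgeR), with 3 counts in *thp1-5*, 40 in Col and 319 in *sac3bc*. The exact 95% counting interval of its ratio between the mutants, 0.00239 to 0.0343, is wider than that standard error implies. *LURP1*, a gene induced by pathogens, differed by −3.48 ± 0.16, with −1.83 ± 0.21 in *thp1-5* and 1.65 ± 0.13 in *sac3bc* against Col. *NATA1* differed by −2.46 (adjusted p = 3.99e-06, edgeR), with −1.27 ± 0.58 (adjusted p = 0.0452) and 1.19 ± 0.39 (adjusted p = 0.00446) against Col. The call of *NATA1* in *thp1-5* was lost without Col replicate 2 (adjusted p = 0.298), Col replicate 3 (0.118), *thp1-5* replicate 2 (0.231), *thp1-5* replicate 3 (0.147) or *sac3bc* replicate 2 (0.0509), with the replicate block (0.0533), DESeq2 (0.106), no filter (0.0524) or total counts (0.115), and that in *sac3bc* without Col replicate 1 (0.0698). *PRX52*, a peroxidase gene, differed by −2.02 (adjusted p = 1.12e-09, edgeR), with −0.98 ± 0.35 (adjusted p = 0.00995) and 1.04 ± 0.25 (adjusted p = 0.000131). The call of *PRX52* in *thp1-5* was lost without Col replicate 1 (adjusted p = 0.0553), *thp1-5* replicate 1 (0.0662) or *thp1-5* replicate 2 (0.0518), and with total counts (0.0658).

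*CHLI1*, which encodes a subunit of the magnesium chelatase of chlorophyll synthesis, stood at 423.6 CPM in Col, 143.3 in *thp1-5* and 410.9 in *sac3bc*, log2 fold changes of −1.56 ± 0.03, −0.04 ± 0.03 (adjusted p = 0.112, edgeR) and, between the mutants, −1.52 ± 0.03. In *sac3bc* it was called lower with RLE factors (−0.06, adjusted p = 0.0289) and the length and GC correction (−0.11, 2.64e-05), and higher with total counts (0.29, 1.9e-22). A lower chlorophyll pathway as the whole cause is argued against by 9 other genes of the pathway, whose median between the mutants was 0.18 (SD 0.0775), although against Col part of it was lower in both, with medians of −0.23 (SD 0.369, 5 called lower and 2 higher) and −0.40 (SD 0.388, 8 lower and 1 higher). A silencing construct against *CHLI1* in the *thp1-5* background may lower this gene alone, and the value of −1.52 leaves this open, since the labels name no construct; an effect of the genotype stays open as well, untested.

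Photosynthesis genes were lower in both mutants. Scaling as the whole cause is argued against by medians of −0.24 or lower with total counts, with 16 and 20 of 21 genes still called lower and 3 and 1 higher. A trend with gene length and GC content is argued against by medians of −0.53 or lower after its removal, with 21 of 21 genes called lower in both mutants. *PYK10*, the most abundant root marker, changed by −1.10 and −1.13. It lay at −4.81 and −4.50 standard deviations of the 8 other root markers from their medians. A smaller share of shoot tissue with unchanged roots would not lower it. This rests on 1 gene whose value was known when the test was set, so it cannot decide on the share of shoot tissue. Since 7 and 8 of the 9 markers rose (medians 0.72 and 1.12), a smaller share, with or without a change within the roots, stays open. Between the mutants, 20 of 21 photosynthesis genes were higher in *thp1-5* and 0 lower, while 6 of 9 root markers were lower and 0 higher, an order that a differing share would also give. A difference in growth or handling between the Col and mutant seedlings follows the groups and was not measured, and an effect of the genotypes stays open, untested.

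*SAC3A* was lower in both mutants, most in *sac3bc*. Reads shared between paralogs are argued against by 0% of its 3054 exonic 50-base stretches occurring elsewhere in the genome. Libraries of another genotype than the label could not be excluded. *SAC3B* was 0.36 higher in *thp1-5* than in *sac3bc*, but *SAC3C*, *THP1* and *SAC3A* were higher there by more. *THP1* is named by the other label and *SAC3A* by neither, so this direction does not check the label. Transcript of *SAC3B* and *SAC3C* was also left, as an insertion may leave it.

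In each single comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05. For *thp1-5* and *sac3bc* against Col and between the mutants, 1 split, the real one, gave as many genes (14297, 15232 and 5150), and the highest of the others gave 0 by edgeR, with up to 388, 323 and 737 genes at an unadjusted p under 0.05. For the genes called in both mutants, 1 of 100 splits of the 9 libraries, the real one, gave as many (12584), a share under 0.05. That rank argues against chance in setting the Col libraries apart. It cannot decide on chance in the grouping of the mutants, since splits that mixed them gave nearly as many. A difference between cultures cannot be excluded either, since the replicates may not be separate cultures. The highest of the other splits gave 11825, 1 of 2 that kept the 3 Col libraries together as the control and mixed the mutants (11825 and 11743), while the rest gave up to 24, so the count mainly shows that the Col libraries stood apart.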

How the results depend on the processing

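The alternatives with total counts, without loci that share exonic bases, and with a length and GC correction were chosen after the data were seen, the others before. The genes called in *thp1-5* and *sac3bc* against Col, between the mutants and in both stayed within 1.5 times the reported counts in 72 of 80 cases. A fold threshold of 2 left 2123, 2817, 233 and 1769 genes, because it adds a condition, and without loci that share exonic bases 9432, 10095 and 8328 (in both) were called among 14505 genes tested, because fewer genes were tested. DESeq2 called 3290 genes between the mutants, 3279 of them shared, and the cause was not tested. Leaving out 1 library gave 13362 to 14372, 14294 to 15346, 4179 to 5171 and 11748 to 12385 genes.

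The replicate numbers paired the libraries weakly at most. Of 9 libraries, 5 correlated best with their own number in both other groups. Correlations ran from −0.00928 to 0.0375 between libraries of the same number and from −0.0344 to 0.0209 between those of different numbers. With the number as a block 14258, 15202, 5093 and 12561 genes were called.

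Of the results for gene lists with camera 1383 kept direction and call, 24 gained a call, 42 lost it and 27 reversed; of those for named genes 3947, 9, 28 and 5. With fry, which compares a list with no other genes, 30 results passed where camera had not, 1 did not pass where camera had, 58 were the same and 4 had the other direction. The estimated correlation ended 31 list calls. For microRNA targets in *thp1-5* the adjusted p was 0.0727 with an estimated correlation, 0.194 without loci that share exonic bases and 0.122 with the length and GC correction, and 0.0341 to 0.0471 when 1 library was left out; the cause was not tested. In *thp1-5* the direction reversed with fry for root markers (adjusted p = 1.52e-05) and snRNAs (0.627), with total counts for microRNA biogenesis (0.355), ribosomal proteins (0.00659) and snRNAs (0.428), and with the length and GC correction for *TAS* precursors (0.689), ribosomal proteins (0.718) and snoRNAs (0.823). In *sac3bc* it reversed with fry for root markers (0.00192) and glucosinolates (0.978), with total counts for microRNA biogenesis (0.434) and *TAS* precursors (0.988), with the length and GC correction for mitochondria (0.875), snRNAs (0.738) and snoRNAs (0.829), and with a mean CPM of 1 for mitochondria (0.886) and snRNAs (0.952). Between the mutants snoRNAs reversed with RLE factors (0.922), without loci that share exonic bases (0.989) and with the length and GC correction (0.737). Leaving out 1 library gave adjusted p-values of 0.807 to 0.962 for *TAS* precursors and 0.758 to 0.966 for snRNAs in *thp1-5*, and of 0.678 to 0.980 for mitochondria and 0.580 to 0.943 for snRNAs in *sac3bc*, with reversals among them; the cause was not tested. Total counts turned *THP1*, *SAC3C* and *HSP90.1* in *thp1-5* to 0.18, 0.11 and 0.056 (adjusted p = 0.120, 0.296 and 0.652) and *CHLI1* in *sac3bc* to 0.29 (1.9e-22), and the length and GC correction turned *HSP70* in *thp1-5* to −0.027 (0.751). *SAC3C* in *thp1-5* passed with the length and GC correction (−0.22, adjusted p = 0.0453). Few counts in 1 group, 1 in Col for *HAC2* and 3 in *thp1-5* for *PR1*, leave the ratios with that group in wide intervals.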

Other observations

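The families below and their tests were chosen after the data were seen. Among 133 families of genes with a common symbol prefix, those with more members changed than other genes were sought by Fisher's exact test, one-sided, counting changes of at least 2-fold against Col and all calls between the mutants. The test takes the members of a family as independent. Related genes may change together or share reads, so the adjusted p-values of families may be too small. In *thp1-5* against Col, 11 of 54 *WRKY* transcription factor genes rose at least 2-fold (adjusted p = 0.00258), as did 7 of 33 cysteine-rich receptor-like kinases (*CRK*, 0.0366), 6 of 26 xyloglucan endotransglucosylase genes (*XTH*, 0.0384), 4 of 11 cytokinin response factors (*CRF*, 0.0384), 4 of 11 *MAPKKK* genes (0.0384) and 4 of 12 *BHLH* genes (0.0499), against 4.78% of 8976 genes. The *BHLH* genes are only those with that prefix. Their result may rest in part on the iron genes *BHLH38*, *BHLH39* and *BHLH100* named above. Lower by at least 2-fold were 20 of 167 genes with the prefix *CYP* (0.00121), 8 of 29 beta-glucosidases (*BGLU*, 0.00121) and 6 of 30 serine carboxypeptidase-like genes (*SCPL*, 0.0366), against 3.83%. The prefix *CYP* was not checked for genes other than those of cytochrome P450. With total counts the calls of *BGLU* (0.269), *CRK* (0.196), *SCPL* (0.269), *MAPKKK* (0.0638) and *BHLH* (0.0839) were lost.

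In *sac3bc*, 12 of 33 *CRK* genes (exact test, adjusted p = 0.000284), 15 of 54 *WRKY* genes (0.000333), 9 of 26 *XTH* genes (0.0032), 5 of 11 glutathione transferases (*GSTF*, 0.0232) and 5 of 13 laccases (*LAC*, 0.0431) rose at least 2-fold, against 6.96% of genes. Lower were 8 of 29 *BGLU* genes (0.0032) and 7 of 30 *SCPL* genes (0.0232), against 4.82%, and with total counts the calls of *SCPL* (0.291), *GSTF* (0.159) and *LAC* (0.0837) were lost. Between the mutants 11 of 14 *PTAC* genes, which encode proteins of the plastid transcription machinery, were called higher in *thp1-5* at any fold change (median 0.18), against 15.3% of genes (exact test, adjusted p = 6.55e-05; 7 of 14 and 0.0194 with total counts).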
